A study of Homo sapiens with 6 samples.

How the data were processed

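RNA of 6 cultures of AGS cells was measured on Clariom S Human arrays, 3 infected with the shCtrl virus and 3 with the shGABRD virus. Per the labels' protocols, the virus was added 24 h after plating and biotin-labelled cRNA was made from 6 ug of total RNA. The authors deposited 1 value table with a log2 expression value for each feature and array. Per the submitters' processing notes, RMA (background correction, quantile normalization and summarisation of probes) and limma were used, with no version. The genome build and the annotation version are not given in the sources used here. That the deposited values are on the log2 scale was read from their range, with medians near 6.18 and maxima from 13.08 to 13.44. Background correction compresses differences of dim features, and quantile normalization gives all arrays nearly the same distribution, so a shift common to most genes cannot be seen in these values.

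The table holds 27189 features. The 5741 control features were left out of the tests and 21448 transcript clusters were kept, with no filter on level. The platform annotation names 17709 of these clusters, each with 1 gene symbol, and 0 with several. The 3739 clusters it does not list were tested but are unnamed here. All 17709 symbols were matched by Entrez identifier to a RefSeq gene table of GRCh38.p14, and 0 changed. This gave 17687 genes, and a gene with several clusters was represented by the cluster with the highest mean over all 6 arrays. All 6 columns of the table were matched to samples.

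Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, 2 groups, no covariate). Differences are shGABRD minus shCtrl on the log2 scale with their SE, and p-values are two-sided and adjusted by the Benjamini-Hochberg method over the 21448 clusters, with 0.05 as the threshold. The median residual SD was 0.138. The labels call the arrays biological replicates but give no separate dates or passages, so p-values measure the spread between these cultures. A 3 against 3 design makes 10 splits of the arrays, so a permutation p cannot fall under 0.1.

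A feature was called above background on an array when it exceeded the 95th percentile of the 612 negative control features of that array, a rule chosen after seeing the data. The threshold was 4.63 to 4.70 on shCtrl arrays and 4.90 to 5.00 on shGABRD arrays. A gene below it on all 3 arrays of a group is called not well above background there. Its difference is given as "at least N-fold", from the bright group's mean and the dim group's mean of the higher of that array's threshold and the gene's own value. For BPIFB1, OLFM4, BPIFA1, F5 and PLOD2, below the threshold on some arrays of a group, the fold is given the same way. The adjusted p beside such a fold is that of the limma test of the deposited values.

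The tests, 33 gene lists, 5 marker lists and the rule for named genes were fixed before the data were examined. Named are GABRD and CCND1, the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold whose group values do not overlap, ranked by the fitted difference with values below background included, so genes at background can rank above genes whose measured change exceeds their bound. Also named are up to 4 members of each list with the smallest adjusted p (2 with the smallest p where none passed), and the measured GABA-A subunits. Lists were tested with camera and a preset inter-gene correlation of 0.01 on 1 cluster per gene, adjusted over the 33 lists, and the marker lists as a separate family of 5. Each list needed at least 5 measured members. Camera was also run with an estimated correlation and on ranks, and fry was run as a self-contained test. Members adjusted over the list alone are counted beside those past the threshold over all clusters. For lists with genes at background, the median was also computed with these genes at their bound.

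The limma step was tested on simulated data with the 21448 clusters and 50 genes planted at each of 4 sizes. It recovered 32% of the genes planted at a log2 difference of 0.5, 72% at 1, 96% at 2 and 100% at 3, with 3 false calls among 153. With only 200 planted genes, the adjusted threshold was stricter than in the data, where 29.1% of clusters passed. These rates therefore do not give the recovery of the main fit. Alternatives were other scalings, filters on dim clusters, variance moderation, array weights, the replicate number as a block, other sets of features, fold thresholds and each array left out in turn. Symbols sharing the letters before their digits were also scanned with camera, after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.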

Results

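Gene expression was measured in AGS cells, an established human gastric adenocarcinoma line of epithelial origin. The cells were infected with a lentivirus carrying either a short hairpin RNA against GABRD (shGABRD) or a control hairpin (shCtrl). GABRD encodes the delta subunit of the GABA-A receptor, a chloride channel opened by the neurotransmitter GABA. Each group had 3 arrays of the Clariom S Human design, named in the labels as biological replicates. The series therefore has 6 arrays and 1 comparison, shGABRD against shCtrl, which asks how transcript levels differed after the hairpin against GABRD. The labels place collection at 48 h after infection, while the culture description adds 72 h of growth after the medium change made 20 h after infection. Which of these times applies to the arrays was not settled. Array medians lay between 6.18 and 6.19 on the log2 scale. Between 71.7% and 77.2% of the 21448 transcript clusters were above background on an array, and the number of arrays limits the precision. Across clusters, Pearson's r was 0.990 to 0.993 between arrays of 1 group and 0.959 to 0.961 between arrays of different groups. Clusters are not independent replicates.

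GABRD, the target of the hairpin, was not well above background in either group. Its values were 4.62, 4.31 and 4.14 on the 3 shCtrl arrays and 4.58, 4.56 and 4.40 on the 3 shGABRD arrays. The means were 4.36 ± 0.24 (SD, n = 3) in shCtrl and 4.52 ± 0.10 (SD, n = 3) in shGABRD. The difference of 0.16 (SE 0.13) did not pass the test by limma (adjusted p = 0.421). All 6 values lay below the array's background threshold, so this probe set cannot check the knockdown, and the groups are those of the labels. Centring the arrays on the hybridization spikes turned the GABRD difference to -0.60, and the negative control features are lowered by the same centring.

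GABA-A receptor subunits gave little signal in these cells. Of 15 measured subunits, GABRD included, 0 passed the test by limma over all clusters and 0 when adjusted over the list alone, and 13 were not well above background in either group (camera adjusted p = 0.567). At an unadjusted p under 0.05, 2 subunits differed by limma, GABRB1 by 0.60 and GABRG3 by 0.39, with adjusted p of 0.0588 and 0.064. GABRB1 passed without shGABRD replicate 2 (adjusted p = 0.00442), and GABRG3, GABRB2 and GABRR1 passed without shGABRD replicate 3 (adjusted p = 0.0478, 0.0404 and 0.0363), all at values below background. With all arrays, GABRB1 also passed with trend and robust moderation (adjusted p = 0.0225) and with array weights (adjusted p = 0.0338). GABRP, the pi subunit found mainly outside the brain, was above background on every array, at 6.30 ± 0.12 in shCtrl and 6.17 ± 0.25 in shGABRD (SD, n = 3; adjusted p = 0.518). Among 15 genes of GABA synthesis, breakdown, transport and GABA-B receptors, 2 rose and 0 fell, with 2 and 0 adjusted over the list alone (camera adjusted p = 0.297). GAD1, which makes GABA from glutamate, rose by 0.44 (SE 0.10, adjusted p = 0.0114 by limma). SLC12A2, a chloride importer, rose by 0.34 (SE 0.08, adjusted p = 0.0184 by limma). The SLC12A2 call was lost without shCtrl replicate 1 (adjusted p = 0.0613), shCtrl replicate 3 (adjusted p = 0.0677) or shGABRD replicate 3 (adjusted p = 0.0592).

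Expression differed widely between the groups. Among the 21448 clusters tested by limma, 6233 (29.1%) passed an adjusted p of 0.05, with 3063 higher and 3170 lower in shGABRD. Of these, 943 had a fitted change of 2-fold or more, 418 upward and 525 downward, values below background included. Counted by gene, 5322 named genes changed, 2567 upward and 2755 downward. Over all 21448 clusters, called or not, the 3 shGABRD values lay on 1 side of all 3 shCtrl values in 9393, an arrangement that chance gives in 10% of clusters. The first principal component separated the groups and held 75% of the variance. Directions are relative to the deposited scaling, in which the median cluster differed by 0.02. Centring on the hybridization spikes, chosen after seeing the data, moved that median to -0.74. It gave 19633 calls, of which 98.1% were lower in shGABRD, against 50.9% lower among the 6233 calls.

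Among the 12 genes with the largest rise in shGABRD, BPIFB1, a secreted airway and mucosal protein, rose by 3.85 on the log2 scale (SE 0.10, adjusted p = 6.44e-07 by limma). DMBT1, a mucosal scavenger receptor protein, rose 11.2-fold, and OLFM4, a marker of intestinal stem cells, rose by 3.41 on the log2 scale. DDIT4, an inhibitor of mTORC1 induced by stress, rose 10.0-fold from 6.89 ± 0.10 to 10.21 ± 0.06 (SD, n = 3). CFTR, the epithelial chloride channel, rose 9.46-fold. PRSS2, a trypsinogen, rose 9.26-fold to 11.90 ± 0.07 (SD, n = 3). LPAR6, a receptor for lysophosphatidic acid, was not well above background in shCtrl and was at least 6.43-fold higher in shGABRD. RNASE1, CLDN2, BMP4, BPIFA1 and F5 rose by 3.17, 3.15, 3.07, 3.01 and 2.87 on the log2 scale. BPIFB1, OLFM4 and BPIFA1 were above background on 2 of 3 shCtrl arrays and F5 on 1 of 3. With shCtrl values below the threshold set to it, these genes were at least 13.7-fold, 9.40-fold, 7.15-fold and 7.10-fold higher. The adjusted p by limma of the 12 genes was 0.00018 or smaller.

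The deepest falls were larger than the largest rises, and several bright genes were at background in shGABRD. DCBLD2, a transmembrane receptor-like protein, had a mean of 10.49 ± 0.03 in shCtrl and 3.78 ± 0.13 in shGABRD (SD, n = 3), at least 46.2-fold lower (adjusted p = 6.57e-08 by limma). UCHL1, a neuronal deubiquitinating enzyme, was at least 52.1-fold lower. NT5E, the cell surface enzyme that makes adenosine from AMP, was at least 31.2-fold lower. AKAP12, a scaffold for protein kinase A, and MAP1B, a microtubule-associated protein, were at least 22.4-fold and 18.4-fold lower. TFPI2, ANXA5, PDPN, HLTF and RDX were at least 17.2-fold, 15.8-fold, 9.72-fold, 6.97-fold and 5.84-fold lower. PLOD2, a collagen lysyl hydroxylase, was above background on 1 of 3 shGABRD arrays and at least 34.2-fold lower with the other values set to the threshold. VIM, the intermediate filament vimentin, was measured in both groups and fell by 4.60 (SE 0.09), or 24.2-fold. The adjusted p by limma of the 12 genes was 2.71e-05 or smaller.

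**Figure D1:**
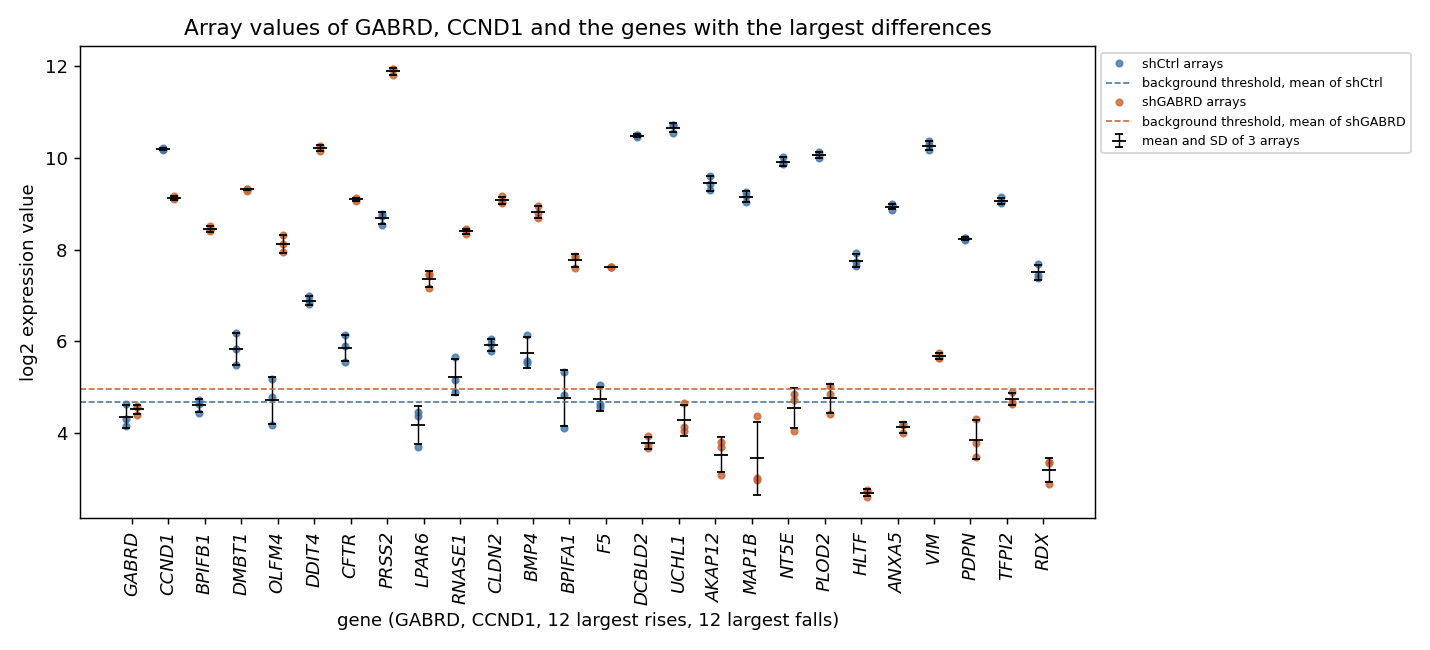
Log2 expression values (vertical axis) of GABRD, CCND1 and the genes with the 12 largest fitted rises and 12 largest fitted falls (horizontal axis), with 1 point per array, blue for shCtrl and orange for shGABRD, and the mean with SD of 3 arrays in black. Dashed lines are the mean background thresholds of each group; GABRD lies below them in both groups, and DCBLD2 moves from 10.49 to 3.78.

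Genes of the entry into S phase fell in part. CCND1, which encodes cyclin D1, fell by 1.06 (SE 0.08, adjusted p = 6.52e-05 by limma), from 10.20 ± 0.03 to 9.13 ± 0.04 (SD, n = 3), a 2.09-fold change. Of 39 genes of DNA replication and the G1/S transition, 0 rose, 26 fell and 13 did not pass, with 0 and 26 adjusted over the list alone. CCNE2 (cyclin E2) fell by 1.97, UHRF1 by 1.08, RRM2 by 0.98 and RRM1 by 0.84. The list's median difference was -0.39 (camera adjusted p = 1.02e-06; adjusted p = 0.127 with an estimated correlation). Among 35 replication-dependent histone genes, 5 rose and 21 fell, the same counts as adjusted over the list alone. H4C8 fell by 1.19 and H4C2 by 1.02, while H3C8 rose by 0.81. The histone list was lower by camera (adjusted p = 0.000567; adjusted p = 0.339 with an estimated correlation).

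Genes of mitosis went both ways. Of 40 genes of G2 and mitosis, 9 rose and 10 fell, with 9 and 12 adjusted over the list alone, and the list did not pass camera (adjusted p = 0.62). PTTG1, the securin that restrains separase, fell by 1.05 and MKI67, the Ki-67 proliferation antigen, by 0.78. The kinetochore genes NDC80 and NUF2 rose by 1.07 and 0.76. Among 22 cyclins, cyclin-dependent kinases and their inhibitors, 4 rose and 5 fell (4 and 6 adjusted over the list alone; camera adjusted p = 0.289). CDKN1B, which encodes the inhibitor p27, rose by 1.53 and RBL2, a pocket protein, by 0.71. Of 29 genes of homologous recombination and the Fanconi pathway, 5 rose and 9 fell (6 and 10 adjusted over the list alone; camera adjusted p = 0.404). NBN fell by 0.95 and RAD51C by 0.80, and FANCF rose by 0.78.

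Ribosome biogenesis genes fell, with the smallest camera p of the 33 lists. Of 25 MYC targets in ribosome biogenesis, 0 rose and 23 fell, the same counts as adjusted over the list alone, with a median difference of -0.58 (camera adjusted p = 4.79e-11; adjusted p = 0.0878 with an estimated correlation). PPRC1 fell by 1.33, SRM (spermidine synthase) by 1.32, UTP20 by 1.22 and NOLC1 by 0.92. Of 33 cytosolic ribosomal protein genes, 2 rose and 11 fell, with 2 and 15 adjusted over the list alone. RPL24 fell by 0.67 and RPL7 by 0.58, and the list was lower by camera (adjusted p = 0.00346; adjusted p = 0.223 with an estimated correlation).

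Heat shock proteins fell, and respiratory chain subunits fell in part. Of 15 heat shock genes, 0 rose and 13 fell, the same as adjusted over the list alone (median -0.58; camera adjusted p = 2.4e-07; adjusted p = 0.0878 with an estimated correlation). HSPB8, a small heat shock protein, fell by 1.90, DNAJA1 by 1.29, HSPH1 by 1.10 and HSPD1, the mitochondrial chaperonin, by 0.84. Of 35 nuclear-encoded genes of oxidative phosphorylation, 0 rose and 19 fell, with 0 and 21 adjusted over the list alone (median -0.29; camera adjusted p = 1.71e-05; adjusted p = 0.0878 with an estimated correlation). NDUFB9 of complex I fell by 0.76, UQCRB of complex III by 0.74 and COX7B of complex IV by 0.73.

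Cholesterol synthesis genes fell in part. Of 20 genes of cholesterol synthesis, 0 rose and 8 fell, the same as adjusted over the list alone, with IDI1 down by 0.84 and NSDHL by 0.79 (camera adjusted p = 0.0129; adjusted p = 0.172 with an estimated correlation). The cholesterol call was lost among genes above the median mean level (adjusted p = 0.0784). In the list of fatty acid synthesis, 3 of 14 genes rose and 7 fell, the same as adjusted over the list alone, and the list did not pass camera (adjusted p = 0.194). ELOVL5, which lengthens polyunsaturated fatty acids, fell by 3.90 on the log2 scale and FADS2, a fatty acid desaturase, by 2.69. ME1, malic enzyme, was at least 2.88-fold lower, and ACSL1 rose by 0.82.

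The ATF4 and amino acid response rose in part. Of its 32 measured genes, 21 rose and 3 fell, with 23 and 3 adjusted over the list alone, and the median difference was 0.68 (camera adjusted p = 3.45e-08; adjusted p = 0.167 with an estimated correlation). CHAC1, which degrades glutathione, rose by 2.60 (SE 0.08) and SLC7A11, the cystine transporter, by 2.14 (SE 0.09). GDF15, a secreted stress cytokine, rose by 1.70. The ER unfolded protein response list did not pass camera (adjusted p = 0.957), with 5 of 22 genes up and 4 down (5 and 5 adjusted over the list alone). HERPUD1 rose by 1.61 and XBP1 by 0.83, while MANF fell by 0.74. The median of that list was -0.05 and its mean 0.05, and camera gave it the negative sign.

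Hypoxia targets and interferon genes rose in part. Of 23 hypoxia targets, 12 rose and 5 fell, with 13 and 5 adjusted over the list alone (median 0.32; camera adjusted p = 0.00626; adjusted p = 0.129 with an estimated correlation). VEGFA, the vascular growth factor, rose by 1.99, MXI1, an antagonist of MYC, by 1.38 and ERO1A by 1.03, while ADM fell by 1.40. Of 37 type I interferon response genes, 15 rose and 3 fell, with 16 and 4 adjusted over the list alone (median 0.23; camera adjusted p = 0.00617; adjusted p = 0.127 with an estimated correlation). IFI44L rose by 2.20, IFI44 by 1.91, IFI6 by 1.57 and IFI27 by 1.33.

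NF-kB targets and inflammatory cytokines fell in part. Of 24 NF-kB targets and cytokines, 3 rose and 12 fell, with 4 and 14 adjusted over the list alone (median -0.36; camera adjusted p = 0.00499; adjusted p = 0.195 with an estimated correlation). IL1B and IL6 were not well above background in shGABRD and were at least 4.75-fold and 3.79-fold lower, and IL1A was at least 1.32-fold lower. LIF fell by 1.53. The call was lost among genes above the median mean level (adjusted p = 0.145).

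YAP and TEAD targets fell in 10 of 20 genes and rose in 2, with 11 and 2 adjusted over the list alone. CCN1 (CYR61), a matricellular protein, fell by 3.32 (SE 0.10), F3 (tissue factor) by 1.38 and DLC1 by 1.25. DLC1 was above background on 2 of 3 shGABRD arrays. The list's median was -0.39, or -0.26 with the genes at background set to their bound (camera adjusted p = 0.000567; adjusted p = 0.127 with an estimated correlation).

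Targets of the MAPK, Wnt and TGF-beta pathways went both ways, and these 3 lists did not pass camera. Of 27 MAPK feedback and immediate early genes, 10 rose and 6 fell (10 and 7 adjusted over the list alone; adjusted p = 0.957). FOSL1 fell by 2.44, DUSP5 was at least 4.30-fold lower, and ETV5 rose by 1.31. The MAPK list had a median of -0.05 and a mean of -0.06, and camera gave it the positive sign. Of 21 Wnt targets, 7 rose and 5 fell (9 and 5 adjusted over the list alone; adjusted p = 0.363). DKK1, a secreted Wnt antagonist, fell by 2.78 and LGR5, a stem cell receptor, rose by 1.47. Of 19 TGF-beta targets, 3 rose and 7 fell, the same as adjusted over the list alone (adjusted p = 0.289). ID1 rose by 1.85 and SMAD6 by 1.04, both also known as targets of BMP signalling, while CCN2 fell by 1.15 and PMEPA1 by 0.87.

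Mesenchymal genes fell in 10 of 22 and rose in 6, the same as adjusted over the list alone. Beside VIM, PLAU (urokinase) fell by 3.39 (SE 0.12). TNC and FN1, which encode tenascin C and fibronectin, were at least 3.05-fold and 2.26-fold lower. The list passed camera (adjusted p = 0.0347; adjusted p = 0.176 with an estimated correlation). That call was lost on ranks (adjusted p = 0.224) and without shCtrl replicate 1 (adjusted p = 0.059), and among genes above the median mean level the sign turned (adjusted p = 0.427).

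Epithelial genes rose in 9 of 27 and fell in 5, with 14 and 5 adjusted over the list alone. ESRP1, an epithelial splicing factor, rose by 1.56, PKP2 (plakophilin 2) by 1.08 and GRHL2 by 1.08, while KRT7 (keratin 7) fell by 1.89. The epithelial list did not pass camera (adjusted p = 0.0558), but did so without shCtrl replicate 2 (adjusted p = 0.0318), without shGABRD replicate 1 (adjusted p = 0.0419) and after quantile normalization (adjusted p = 0.0291). Of 22 genes of matrix and integrins, 7 rose and 7 fell, the same as adjusted over the list alone (camera adjusted p = 0.496). SPARC was at least 3.51-fold lower, and ITGA6 and ITGA5 rose by 0.99 and 0.92.

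Of 24 gastric differentiation genes, 7 rose and 2 fell, the same as adjusted over the list alone. PGC (pepsinogen C) rose by 1.71, MUC1 by 1.39 and TFF1 (trefoil factor 1) by 1.09, and SOX2 fell by 1.30. The gastric list did not pass camera (adjusted p = 0.0606) except without shGABRD replicate 3 (adjusted p = 0.0499) and among clusters above background (adjusted p = 0.0411). Of 23 intestinal genes, 5 rose and 4 fell (5 and 5 adjusted over the list alone; camera adjusted p = 0.957). ANPEP (aminopeptidase N) fell by 3.19 and AGR2 by 1.68, while TSPAN8 rose by 0.99. The intestinal list had a median of 0.08, a mean of -0.03 and the positive sign by camera.

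In the remaining 6 lists, none passed camera. Of 26 p53 targets, 7 rose and 6 fell (7 and 7 adjusted over the list alone; adjusted p = 0.957), with SESN2 up by 1.36, SESN1 by 0.84 and TNFRSF10B, a TRAIL receptor, by 0.75. The p53 list had a median of -0.02, a mean of 0.05 and the positive sign by camera. Of 24 BCL2 family and caspase genes, 8 rose and 3 fell (9 and 4 adjusted over the list alone; adjusted p = 0.289). CASP10 rose by 0.90 and APAF1 by 0.73, and PMAIP1 (NOXA) fell by 0.76. Glycolysis genes rose in 6 of 21 and fell in 6, the same as adjusted over the list alone (adjusted p = 0.874). HK2 (hexokinase 2) rose by 1.02 and TPI1 fell by 0.69. Lysosome and autophagy genes rose in 11 of 25 and fell in 3 (13 and 4 adjusted over the list alone; adjusted p = 0.11), with WIPI1 up by 1.10 and CTSZ down by 1.61. NRF2 targets rose in 5 of 21 and fell in 3 (8 and 4 adjusted over the list alone; adjusted p = 0.19), with ABCC3 up by 0.80. Of 12 genes of microRNA processing, 2 rose and 4 fell, the same as adjusted over the list alone (adjusted p = 0.289). AGO2, the slicing Argonaute, fell by 0.59 and AGO4 rose by 1.07.

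By camera with the preset correlation, 13 of the 33 lists passed, 3 higher and 10 lower in shGABRD. With an estimated correlation 0 passed. Fry, which tests whether a list's genes move on balance in 1 direction, called 27. In other splits of the 6 arrays, which mix the groups, camera with the preset correlation passed up to 7 lists.

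**Figure D2:**
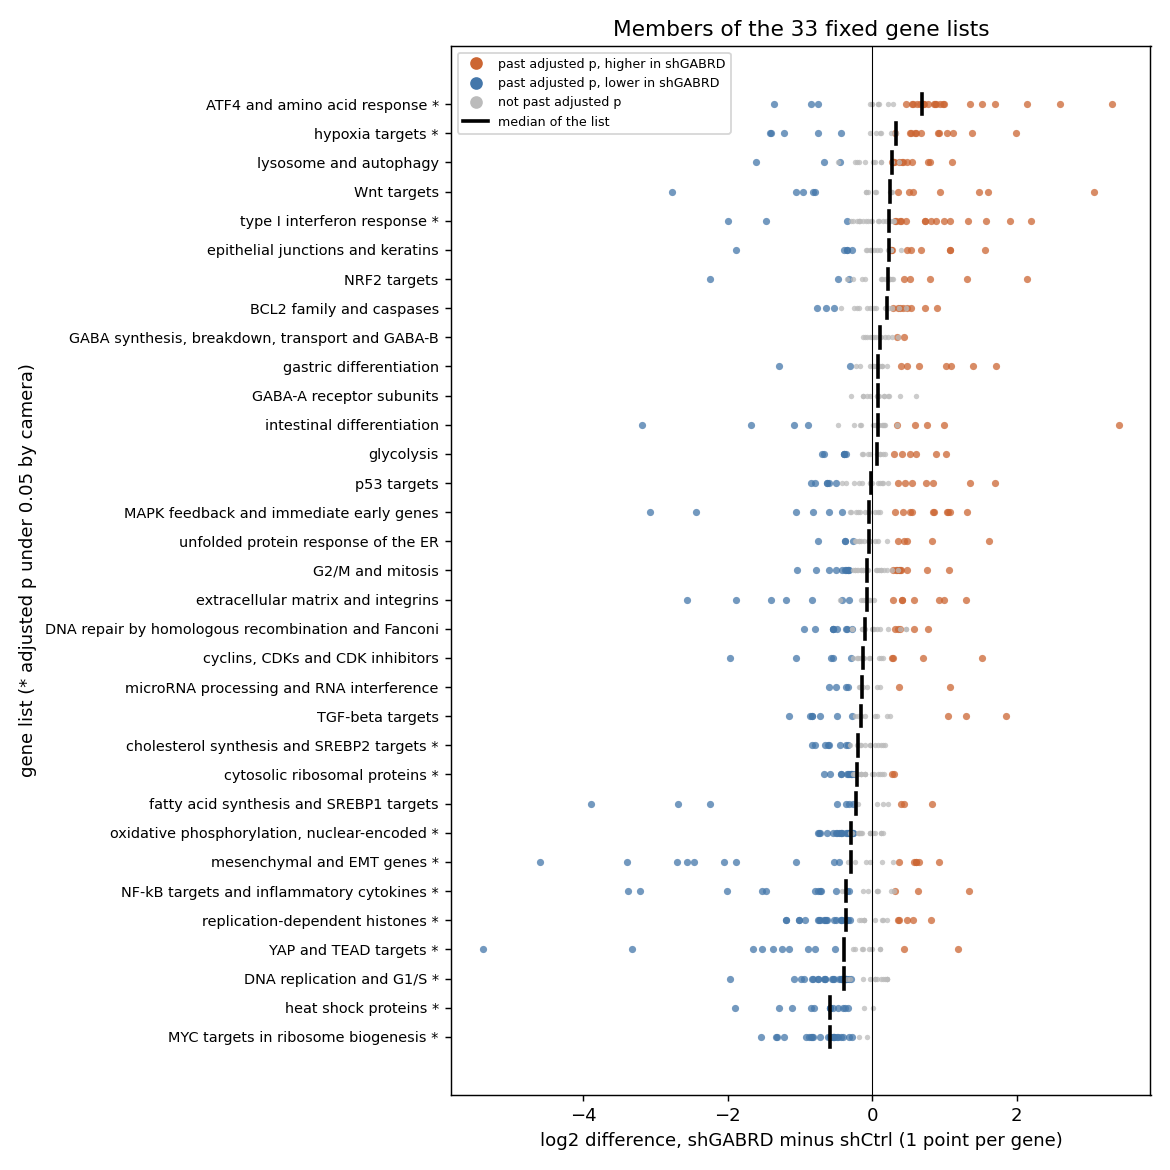
Log2 difference, shGABRD minus shCtrl (horizontal axis), of each measured member of the 33 gene lists (vertical axis), with 1 point per gene, orange or blue where it passed an adjusted p of 0.05 by limma and grey where it did not. Black bars are list medians, from -0.58 for MYC targets in ribosome biogenesis to 0.68 for the ATF4 and amino acid response, and an asterisk marks the 13 lists past camera with the preset correlation.

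Markers of other cell types did not move as groups. None of the 5 marker lists passed camera (adjusted p = 0.967 for each; 0 with an estimated correlation). Of 11 fibroblast markers, 1 rose and 0 fell, and of 12 leukocyte markers 1 rose and 1 fell. Of 9 endothelial markers and of 9 markers of an embryonic kidney packaging line, 0 changed by limma, and of 9 neuronal markers 1 rose and 1 fell. The counts adjusted over the list alone were the same. PDGFRA, a growth factor receptor, rose by 0.77. LYZ, which encodes lysozyme and is also made by gastric epithelium, rose by 1.54 to 13.05 ± 0.04 (SD, n = 3), while CD68 fell by 0.42. MAP2, a microtubule-associated protein, rose by 0.83 and RBFOX3 fell by 0.39. EYA1 of the kidney line list, which differed by -0.31 (adjusted p = 0.0762 by limma), passed among clusters above the 25th percentile (adjusted p = 0.048), among clusters above background (adjusted p = 0.0468) and with cyclic loess (adjusted p = 0.0446). LIN28B of that list, below background in both groups, passed without shGABRD replicate 2 (adjusted p = 0.044). The CD68 call was lost without shCtrl replicate 1 (adjusted p = 0.0514). The RBFOX3 call was lost without any of 5 arrays, with adjusted p from 0.0781 to 0.113.

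Control features also differed between the groups. The 18 hybridization spikes, bacterial and phage transcripts added to the hybridization mix, were higher on the shGABRD arrays, with a mean of 11.30 ± 0.04 against 10.54 ± 0.05 (SD, n = 3). Negative control features differed by 0.18, poly-A spikes by -0.24 and housekeeping control features by -0.19 (medians of shGABRD minus shCtrl). The share of clusters above background was 71.7% to 73.2% on shGABRD arrays and 76.6% to 77.2% on shCtrl arrays. These differences ran with the groups.

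**Figure D3:**
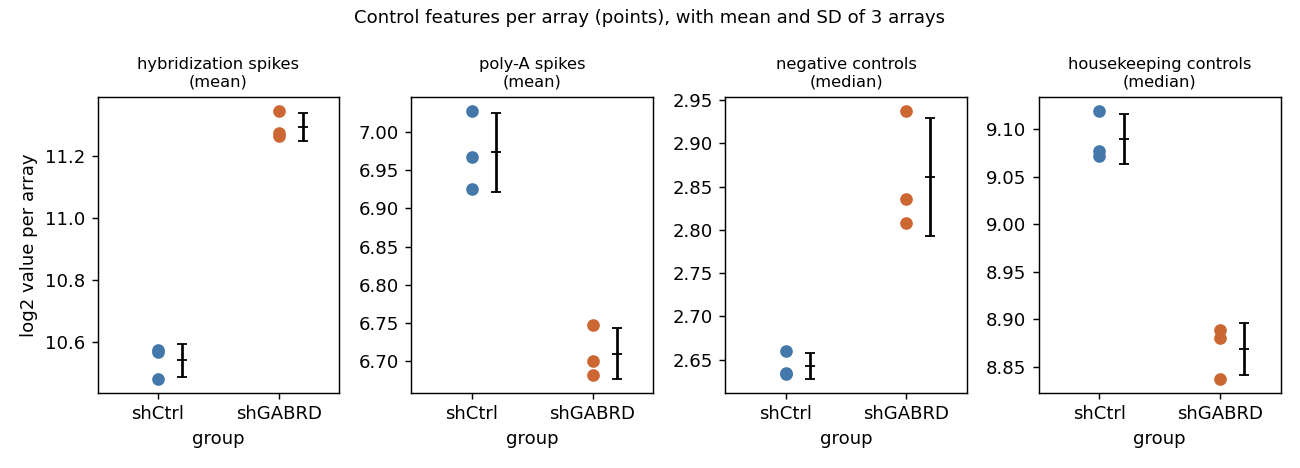
Log2 level per array (vertical axis, scaled separately in each panel) of 4 classes of control feature in shCtrl (blue) and shGABRD (orange), with the mean and SD of 3 arrays in black. The hybridization spikes stand at 10.48 to 10.57 in shCtrl and 11.26 to 11.35 in shGABRD, with no overlap between the groups in any of the 4 panels.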

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

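The tests of GABRD at background, of wrong array labels, of the control features, of the scaling and of pairs of arrays within a group were chosen after the results were seen. The scaling test replaces 1 written beforehand, in which all 79 lost and all 6 gained clusters kept a difference of 2 under quantile normalization and under median centring. The test written beforehand does not decide, because the deposited values were already quantile normalized and the clusters were chosen for such a difference. In its replacement the clusters of like brightness set beside them were not chosen for a difference. The tested clusters were the same, so the outcome was again largely fixed by their choice, and the replacement does not decide either. The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. Only the real split gave as many clusters past the threshold (1 of 10, 6233 clusters, highest other 0), and the same holds for the lists past camera (1 of 10, 13 lists, highest other 7).

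Among the reporter control features, 3 had a signal above background on all arrays and were higher in shGABRD at an adjusted p under 0.05 by limma. What these features detect in these cells was not examined. Their differences were 0.61, 0.54 and 0.30. The 3 brightest reporter features were lower in shGABRD, by -0.61, -0.64 and -0.55, from means of 13.01, 12.62 and 12.13 in shCtrl.

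GABRD was not lower in the arrays labelled shGABRD. A single array under the wrong label is argued against, since 0 of 6 arrays correlated best with an array of the other group. GABRD lay below the threshold on 6 of 6 arrays, so this probe set cannot show whether GABRD was lowered. An exchange of all labels between the groups, and a hairpin that did not lower GABRD, stay open, and neither was tested.

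A set of 85 clusters was above background on all 3 arrays of 1 group and not well above it in the other. Their fitted values differed 4-fold or more, and 79 were lost in shGABRD against 6 gained. The background threshold was higher on shGABRD arrays (4.90 to 5.00) than on shCtrl arrays (4.63 to 4.70), which makes a loss easier to call than a gain. A mixture with the cell types of the marker lists is argued against by their lowest median of -0.12. Whether a scaling that moves clusters of like brightness together plays a part stays open for the 79 lost and the 6 gained. The clusters were chosen for a large difference, so the comparison with clusters of like brightness does not decide. The values for the 79 lost are given first. Their median difference relative to the 50 other clusters nearest in brightness was -2.77, and those clusters had a median difference of 0.03. Of the lost, 98.7% differed from them by at least 2 on the log2 scale, and 79 of 79 kept such a difference with spike centring. That centring lowers shGABRD relative to shCtrl, so it can only deepen a loss and shrink a gain. Of the 6 gained, 100% differed by at least 2 (median 2.40), and 2 of 6 kept this with spike centring. Cells of different origin in the groups may also give such a pattern, for which differences of genes 20 to 50 genes apart on a chromosome correlated at 0.0185, above all 1000 permuted orders (highest 0.00523), which meets what had been written beforehand for that explanation, but 1 pair of arrays within a group reached 0.0299, so the test was not specific and was set aside after that value was seen. An effect of the GABRD hairpin, named by the design, an off-target effect of its sequence and cells of different origin cannot be told apart here, because each group is 1 construct in its own cultures.

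All 18 hybridization spikes were brighter on the 3 shGABRD arrays than on the 3 shCtrl arrays, by 0.37 to 0.95 (median 0.88). Weaker target signal that the authors' normalization scaled up is consistent with the negative control features, which rose by a median of 0.18 and were higher on all 3 shGABRD arrays, and with the poly-A spikes, which did not rise (-0.24). A hybridization batch that coincides with the groups would give the same spike difference of 0.88 and cannot be told apart from it, because the labels give no hybridization batch. No biological explanation was tested.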

How the results depend on the processing

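Above-background filtering, centring on the hybridization spikes and cyclic loess were chosen after seeing the data. The number of calls (6233) stayed within 1.5 times under 11 settings that change scaling, filter, moderation, weights, block or features, from 5467 to 7896, and from 4675 to 5523 with an array left out. These are counts, not shares, since the settings test different numbers of features. Above the median mean level 5720 of 10724 passed, and with control features kept in 7896 of 27189. Quantile normalization kept 6040 of the calls and cyclic loess 5909, all in the same direction. A fold of at least 1.5 left 2817 calls, 1312 higher and 1505 lower, and a fold of at least 2 left 943, 418 higher and 525 lower, by construction. The replicate numbers gave no clear pairing of the arrays. Deviations from the group means correlated at 0.07, 0.06 and -0.002 for equal numbers and from -0.07 to 0.01 for unequal numbers. A weak effect shared by replicates is not excluded. With the replicate block 5725 clusters were called, GABRG3 passed (adjusted p = 0.026), and no list changed its call.

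Centring on the hybridization spikes shifted every difference down, giving 19633 calls, 378 higher and 19255 lower. Under it, GABRD stood at -0.60 (adjusted p = 0.00451), against an adjusted p of 0.107 to 0.826 with an array left out of the deposited scaling. The sign also turned for GAD1 (-0.31), SLC12A2 (-0.42), RBL2 (-0.050), TNFRSF10B (-0.0084), APAF1 (-0.026), SEL1L (-0.28), SLC2A3 (-0.15), EMCN (-0.49), GABRB1 (-0.15), GABRB2 (-0.52), GABRG3 (-0.37), GABRR2 (-0.69), GABRR3 (-0.68), GABRQ (-0.66), GABRA3 (-0.60), GABRA4 (-0.69) and GABRA5 (-0.54). A further 16 named genes that rose no longer passed. This follows from the construction of the setting, which subtracts 1 amount per array. The 3 lists higher by camera had medians of 0.68, 0.32 and 0.23, smaller than the gap between the mean spike levels (11.30 against 10.54). Their rise is therefore relative to the deposited scaling, and the lists were not run under this setting.

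Among genes at background, GABRR3 turned to -0.015 with array weights and ranged from -0.0949 to 0.363 with an array left out, GABRA4 from -0.126 to 0.226 and GABRA6 from -0.0763 to 0.0589. The sign of lists that did not pass turned as follows, and the cause was not tested. For the unfolded protein response, adjusted p was 0.00613 by fry, 0.875 after quantile normalization, 0.969 above the median level, 0.74 with cyclic loess and 0.961 above background (0.836 to 0.991 with an array left out). The MAPK list had 0.00918 by fry (0.836 to 0.992 with an array left out), the intestinal list 0.00135 by fry and 0.944 above the median level (0.864 to 0.991), the p53 list 0.927 on ranks (0.836 to 0.991) and the matrix list 0.561 above the median level. The mesenchymal list turned above the median level (0.427) and lost its call above background (0.0778). Cyclic loess added calls for the epithelial (0.0142) and lysosome (0.0414) lists. Lists past the threshold numbered 0 with an estimated correlation and 27 by fry. Signal over background limits the 13 dim GABA-A subunits and the 435 called clusters not well above background in 1 group.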

Other observations

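The gene groups here were found by scanning all 613 symbol stems (the letters before the first digit) with at least 5 genes, and the single genes were chosen after their values were seen. By camera with the preset correlation 14 stems passed, and with an estimated correlation the smallest adjusted p was 0.862. Metallothioneins, small proteins that bind zinc and copper, fell more than any other stem by camera p (adjusted p = 2.36e-12; adjusted p = 0.862 with an estimated correlation). Of 13 measured genes of the stem MT, 12 fell and 0 rose, with a median difference of -2.78. MT1E fell by 4.06 (SE 0.10), MT1B by 3.21 and MT2A by 3.01 from a mean of 12.84 (n = 3 arrays per group; adjusted p = 7.81e-07 for MT2A by limma), while MT3 differed by -0.29 and did not pass. The direction held under quantile normalization, median centring, cyclic loess and spike centring, with medians from -2.72 to -3.54. The zinc exporter SLC30A1 and the metal-responsive transcription factor MTF1 fell by 0.44 and 0.37. MT1 genes are closely similar in sequence, and cross-hybridization between their probe sets was not examined.

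Clustered protocadherins of the beta group, adhesion proteins encoded side by side, rose in 11 of 16 measured genes and fell in 0 (median 0.46; camera adjusted p = 0.00121; adjusted p = 0.942 with an estimated correlation). PCDHB14 rose by 0.88 and PCDHB3 by 0.71, while PCDHB1 and PCDHB4 passed below background in both groups. The direction of this group flipped with centring on the hybridization spikes (median -0.30). All 5 measured glutathione S-transferases of the mu class rose (median 0.79; camera adjusted p = 0.00328; adjusted p = 0.942 with an estimated correlation), with GSTM3 up by 1.35, and their median was 0.03 with spike centring. Stems of RNA polymerase subunits, mitochondrial ribosomal proteins and mitochondrial import proteins fell by camera. These were 20 of 30 POLR genes, 25 of 47 MRPL genes and 9 of 15 TIMM genes, with 1, 0 and 0 that rose (adjusted p = 0.942 with an estimated correlation for each).

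Among genes above background on all shCtrl arrays and not well above it on any shGABRD array, CD274, which encodes the immune checkpoint ligand PD-L1, was at least 4.0-fold lower. ZEB1, a repressor of epithelial genes, and CDH2, N-cadherin, were at least 3.53-fold and 1.76-fold lower. MAGED1, GLIPR1 and TUSC3 were at least 4.56-fold, 8.94-fold and 6.79-fold lower. In the other direction SORBS2, an adaptor of the actin cytoskeleton, was at least 5.82-fold higher in shGABRD.

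Along the chromosomes, in a check chosen after seeing the data, medians were taken over 648 windows of 40 neighbouring genes ordered as in GRCh38.p14. The lowest was -0.33, on chromosome 3 from MBNL1 to FNDC3B, where 32 genes were lower and 8 higher in shGABRD. The lowest window of 1000 permuted orders was -0.37. The highest was 0.30, on chromosome 1 from PACC1 to NVL, beside a highest permuted value of 0.29. In units of the median absolute deviation these windows stood at -0.96 and 0.88, and windows of pairs of arrays within a group reached 0.97. In these units neither exceeds what arrays of 1 group give. Differences within a group are narrower on the log2 scale (SD 0.22 to 0.27 for a pair of arrays, against 0.53 to 0.54 between groups). The check therefore does not decide on regional shifts.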
